A study of Gallus gallus with 4 samples.

How the data were processed

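The data are c-Myc chromatin immunoprecipitation sequencing of primary chicken embryo myoblasts and of myotubes differentiated from such cells, with 1 c-Myc and 1 IgG library per cell state, 4 libraries in all. Base calling with CASAVA 1.8.2, trimming with Trimmomatic 0.30, quality reports with FastQC 0.10.1, alignment with Bowtie2 2.1.0 and peak analysis with HOMER 4.6 on genome build galGal4 are named per the submitters' processing notes, which give no order or options. Peaks were called for each cell state from its c-Myc library against its IgG library and then annotated, per the file headers; the peak calling options are not given in the sources used here. Paired reads appear to count 0.5 tags each, since every tag value is a multiple of 0.5.

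Each row of the deposited peak lists is 1 peak of fixed width (200 bp in myoblasts, 154 bp in myotubes). The score of a peak is the authors' own, and it equals c-Myc tags per 10M tags of the library within 0.05, so that scores of both lists share a scale of depth but are counted over peaks of different width, and no score is corrected for width; a further score, the caller's own, is in tags. The signal columns give c-Myc and IgG tags per peak without scaling, and IgG tags scaled to the c-Myc library, per the file headers. The fold over IgG and the fold over the local region are ratios as deposited by the authors; every listed peak has both at 4.0 or above. The p-value against IgG per peak is that of the authors' caller, with a highest listed value of 8.09e-05 in myoblasts and 5.50e-05 in myotubes. The IgG tags counted over a peak and the scaled IgG tags behind its fold can differ (3.5 and 0.4 at CDC25A in myoblasts), so folds of single genes are not printed. Distances to the nearest annotated TSS, the annotation class and the nearest gene are the authors' annotation, which for each peak names a single nearest gene; for microRNA genes that position is the start of the precursor.

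From these lists the number, width and tags of peaks were summed, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9. A myotube peak counted as shared when it overlapped a myoblast peak by at least 1 bp (bedtools 2.31.1), and the number was set against 1000 seeded random placements on the same chromosome up to the last peak end on it. A gene was a target when a peak assigned to it lay within 1 kb of its TSS. Shares carry exact (Clopper-Pearson) 95% intervals. Shares of peaks and genes were compared by two-sided Fisher exact tests with Benjamini-Hochberg adjustment over annotation classes, chromosome classes or the 25 gene lists of a cell state; an adjusted p under 0.05 was called. Other comparisons used permutation tests with 100000 resamples.

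The background of gene tests was the 4834 genes named in either peak list, of which 4792 (99.1%) match a gene of the RefSeq table of the newer assembly GRCg7b, used for names only. This background holds only genes with some peak nearest to them; the wider one adds all genes with a curated transcript in that table, 7233 in all, including genes that the authors' annotation may not have held. Members of lists were matched by exact symbol, since older symbols are shared between paralogs, and a gene not named in the lists counts as not measured; 25 lists with 638 entries were used. The genome sequence of the authors' build was not used here, so E-box motifs under peaks were not counted, and the share of promoter windows in the spanned sequence (1.45%) assumes that windows do not overlap and that each gene has 1 TSS.

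Most tests, the symbols in the lists, the rule for named genes and most alternatives were fixed before the data were examined. Exact matching of symbols was not: members were first matched through older symbols as well, and this was changed after the first results had been seen, which affects the members and p-values of every list. The rule took MYC and all members of its network and of the myogenic regulators with any assigned peak, the 10 promoter peaks with the highest score in each list, the 10 highest myotube peaks without a myoblast overlap, and up to 4 members of each other list with the highest promoter peaks in each state; ties went by chromosome and start. Not every gene that the rule took is named. Further genes named are targets of both states, the remaining splicing genes and H2AFZ, chosen after their values were seen. Alternatives were other overlap rules, TSS windows of 500 bp and 5 kb, the nearest gene at any distance, a stricter fold, the upper 50% of each list by score, as many top myoblast peaks as myotube peaks, and leaving out unplaced sequence; a wider gene background, a list without repeats and a null of shifted peaks were added after seeing the data.

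The counting was tested on simulated data. With 200 of 1061 simulated myotube peaks planted on myoblast peaks, 203 were found shared, and with none planted 7 were found against a random mean of 8.14. In 100 simulated draws over the 4834 genes, a myoblast list of 20 genes with 12 targets was called in 100, and 7 of 2400 unplanted lists were called. The planted list held the same counts in every draw, so its unadjusted p was fixed and its calls do not measure power. Smaller lists, smaller excesses and myotube lists were not simulated.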

Results

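The study mapped the transcription factor c-Myc on the chicken genome in skeletal muscle cells and asked which genes it targets in myoblasts and in myotubes. c-Myc is a helix-loop-helix leucine zipper protein that binds DNA with its partner MAX and is known for driving growth and proliferation. Myoblasts are the dividing, mononucleated precursors of muscle fibres, and myotubes are the multinucleated cells that they form by fusion after leaving the cell cycle. Primary cells at passage 1 were taken from embryonic skeletal muscle, grown in 15% fetal bovine serum as myoblasts, and moved to 2% horse serum for differentiation. Chromatin immunoprecipitation followed by sequencing gave 1 c-Myc library and 1 IgG library in each cell state. The c-Myc libraries held 11.5M tags (M for 1e+06) in myoblasts and 8.65M in myotubes, and the IgG libraries held 16.1M and 19.3M. No library had a replicate, so every difference between the cell states is a difference between single libraries, and each p-value below compares lists of peaks or genes, which are not replicates of a condition. Intervals are exact 95% binomial intervals and cover counting error only.

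c-Myc peaks lay within 1 kb of the transcription start site (TSS) of 1063 genes in myoblasts and of 66 genes in myotubes. In myoblasts these included NCL, which encodes the nucleolar protein nucleolin, and LDHA, a subunit of lactate dehydrogenase. AMD1, an enzyme of polyamine synthesis, and PLK1, a mitotic kinase, were also among them. Like 1045 of the 1063 genes, these had no promoter peak in myotubes, which does not show a loss of binding. Scaled for depth and peak width, myoblast peaks needed at least 19.0 tags to reach 11, the lowest caller score in myotubes. The peaks at NCL, LDHA and PLK1 held fewer tags than that, and the peak at AMD1 held more. CDC25A, which encodes a phosphatase that activates cyclin-dependent kinases, had a promoter peak in both states, at 16.1 c-Myc tags per 10M in myoblasts and 12.7 in myotubes. Over the genome, 19354 peaks were called in myoblasts and 1061 in myotubes, an 18.2-fold difference in number with no replicate to test it. The peaks covered 3870.8 kb and held 2.57% of c-Myc tags and 0.330% of IgG tags in myoblasts, against 163.4 kb, 0.157% and 0.0189% in myotubes. The authors' peak score, which equals c-Myc tags per 10M, had a median of 12.6 over the wider peaks of myoblasts and 13.3 over those of myotubes, so that the typical called peak held 14.5 and 11.5 tags. Counting error alone puts 14.5 tags between 8.02 and 24.1 and 11.5 tags between 5.84 and 20.3, and single peaks were therefore measured coarsely.

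Among the 10 strongest promoter peaks in myoblasts, those at UBE2A, a ubiquitin-conjugating enzyme, and WDR1, a factor of actin disassembly, had 27.5 tags per 10M each, and that at RPS3A, a protein of the small ribosomal subunit, had 26.1. The UBE2A peak lay on chromosome 4 of galGal4 from 16513237 to 16513437. UQCR11, a component of respiratory complex III, had 25.3, and CTGF, a secreted matricellular protein, ZFYVE21 and FUBP1 had 24.8 each. FUBP1 encodes a protein that binds the far upstream element of MYC, and its peak lay on chromosome 8 from 17790583 to 17790783. ATG7, an enzyme of autophagy, and NSFL1C, a cofactor of the ATPase p97, had 24.4. These peaks held between 28 and 31.5 c-Myc tags, against 1.5 to 6.5 tags in the deeper IgG library.

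In myotubes the strongest promoter peaks were at CD8B, a T-cell coreceptor, with 25.4 tags per 10M, and TGIF1, a repressor of TGF-beta signalling, with 22.5. PLA2R1, a phospholipase receptor, had 18.5, and C1H7ORF60, IQCC and ERP29, a protein of the endoplasmic reticulum, had 17.3 each. GYG1, which encodes glycogenin, the primer of glycogen synthesis, had 16.8. COX4I1, a subunit of cytochrome c oxidase, and MDH1, the cytosolic malate dehydrogenase, had 16.2, and RBL2, the retinoblastoma-related protein p130, had 15.6. COX4I1, MDH1 and RBL2 were the members of these 10 that also had a promoter peak in myoblasts, at 15.7, 10.9 and 13.5. The MDH1 peak held 14.0 c-Myc tags and 0 IgG tags, whereas the CD8B peak held 22.0 and 7.0. The IgG library of myotubes was more than 2 times as deep as its c-Myc library.

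Few called peaks were shared between the lists of the cell states. The lists were called separately, so a site missing from a list may still be bound in that state. Without replicates, the overlap expected between libraries of the same state is not known. At least 1 bp of a myoblast peak was met by 74 of the 1061 myotube peaks (6.97%, 5.52 to 8.68%), among them promoter peaks at CDC25A, CSNK1D, FAM98A, MDH1, NFAT5, RAD18, RBL2, RPL12 and WDR1. CSNK1D is a casein kinase of the circadian clock, NFAT5 a transcription factor of the osmotic stress response, RAD18 a ubiquitin ligase of DNA damage tolerance and RPL12 a ribosomal protein. The CDC25A peaks lay on chromosome 2 from 565279 to 565479 in myoblasts and from 565348 to 565502 in myotubes. The WDR1 peak had 27.5 tags per 10M in myoblasts and 12.7 in myotubes, and the MDH1 peak 10.9 and 16.2, without correction for the wider peaks in myoblasts. Random placement of the myotube peaks on their own chromosomes met 7.93 ± 2.85 myoblast peaks (SD over 1000 placements, highest 19), 9.33-fold fewer than observed (one-sided permutation p = 0.000999, the smallest that 1000 placements can give). Of the shared peaks, 34 were labelled as simple repeats, low-complexity sequence or structural RNA genes, and without peaks so labelled 39 were shared.

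**Figure D1:**
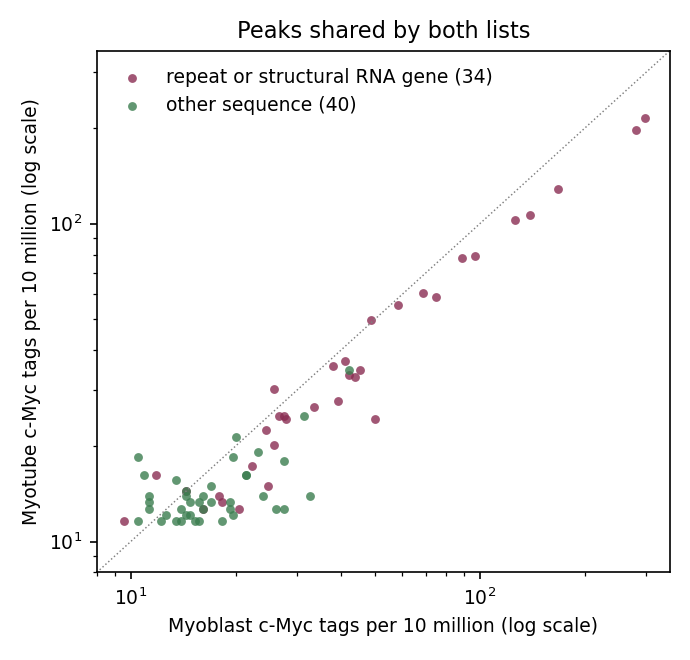
c-Myc tags per 10M at the 74 pairs of overlapping peaks in myoblasts (x axis, log scale) and myotubes (y axis, log scale), 1 point per pair; purple points lie in simple repeats, low-complexity sequence or structural RNA genes (34) and green points in other sequence (40), and the dotted line marks equal values; myoblast peaks are wider, and no correction for width was made. The pairs with the most tags are in repeats, up to 297.2 in myoblasts and 214.4 in myotubes.

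Of the 987 myotube peaks with no myoblast peak at the same place, 21 (2.13%) lay in simple repeats, low-complexity sequence or structural RNA genes, against 45.9% of the shared peaks. Of the 10 with the highest score, 6 lay in simple repeats, including those nearest to PCK1, the gluconeogenic carboxykinase (41.6 tags per 10M, 15.5 IgG tags), RPRD1A (27.2), SWAP70 (26.6), MND1 (25.4) and LDB1, a LIM-domain cofactor (24.9). Another, nearest to LOC425783, lay in a CR1 LINE element. The strongest, with 42.8, was in intron 3 of the transcript annotated for the microRNA gene MIR3524B on chromosome 1 from 117865219 to 117865373 and held 37.0 c-Myc and 20 IgG tags. Of the 10, only the peaks at CD8B and TGIF1 lay within 1 kb of a TSS.

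Around genes, the peaks of both cell states were densest just upstream of the TSS. Of the myoblast peaks 5.71% (5.39 to 6.05%) lay within 1 kb of a TSS and of the myotube peaks 6.31% (4.93 to 7.95%), while the windows of the 7233 genes used as the wider background cover about 1.45% of the 1000.2 Mb that the peaks span. Myotube peaks without a myoblast overlap had a promoter share of 5.78%, against 5.71% of myoblast peaks (odds ratio 1.01, 0.755 to 1.33, two-sided Fisher exact test p = 0.944). Intergenic sequence held 77.1% of myoblast and 77.0% of myotube peaks and introns 13.6% and 12.1%. None of the 7 annotation classes differed between these myotube peaks and the myoblast list at an adjusted p under 0.05, with a lowest adjusted p of 0.544. Against the 1061 myoblast peaks with the highest score, of which 14.2% lay within 1 kb of a TSS, the share of myotube peaks that overlapped none of them was lower by 7.83 percentage points (Fisher exact p = 4.08e-09), a comparison of the strongest peaks of a long list with most of a short list.

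**Figure D2:**
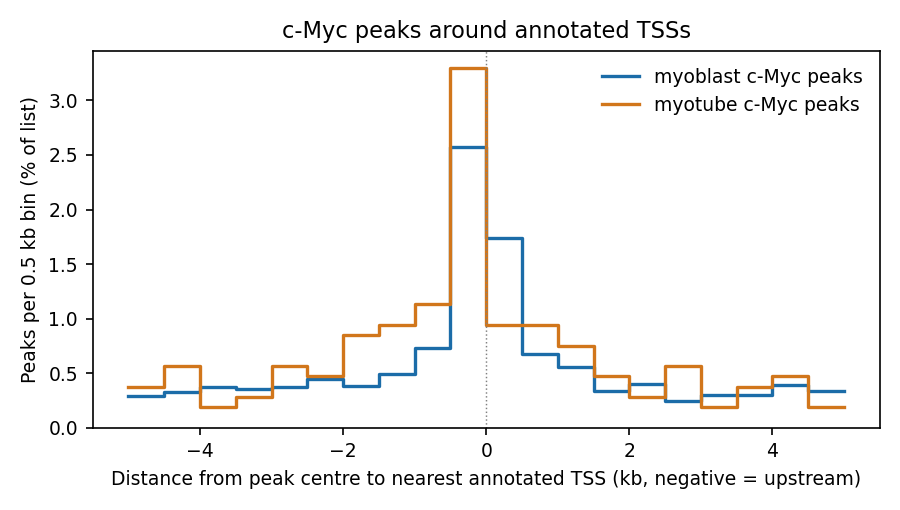
Share of c-Myc peaks (y axis, percent of each list) in 0.5 kb bins of the distance from the peak centre to the nearest annotated TSS (x axis, kb, negative values upstream) for the 19354 myoblast and 1061 myotube peaks. The bin just upstream of the TSS holds 2.57% of myoblast and 3.30% of myotube peaks.

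Microchromosomes, which are short, gene-dense and GC-rich in birds, carried 29.2% of myotube peaks and 22.2% of myoblast peaks (two-sided Fisher exact test, adjusted p = 1.09e-06 over 4 chromosome classes). Macrochromosomes 1 to 5 carried 50.7% and 57.9% (exact test, adjusted p = 8.52e-06). Peaks per Mb of microchromosome were 25.1 in myoblasts and 1.81 in myotubes, against 18.6 and 0.890 on macrochromosomes. The Z sex chromosome had 6.87 and 0.294 peaks per Mb, and its share of peaks, 2.90% and 2.26%, did not pass the test (exact test, adjusted p = 0.342). The difference for microchromosomes depended on which myoblast peaks were compared: it was 3.35 percentage points with Fisher exact p = 0.0664 in the upper 50% of each list by score, and against the 1061 strongest myoblast peaks the myotube share was lower by 5.37 percentage points, with p = 0.00908.

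The 18 genes with a promoter peak in both states included CDC25A, COX4I1, CSNK1D, FAM98A, LSG1, MDH1, MIR1600, MIR6618, NFAT5, NUBP2, RAD18, RBL2, RPL12, SRRM1, SRSF6, SSRP1 and WDR1. Their peaks overlapped at 10 genes and lay apart at 8. For MIR1600 and MIR6618 the distance is from the start of the precursor, which need not be the promoter. At SRSF6, a splicing factor, the peaks were centred 202 bp downstream of the TSS in myoblasts (13.1 tags per 10M) and at -235 bp in myotubes (15.6), and at SSRP1, a subunit of the histone chaperone FACT, at 862 bp (16.1) and -187 bp (12.7). Independent lists of these sizes would share 14.5 of the 4834 genes named in either list, and the excess did not pass the test (two-sided Fisher exact test, odds ratio 1.34, p = 0.296). Over the 7233 genes that also include every gene with a curated transcript, 9.70 would be shared (odds ratio 2.20, Fisher exact p = 0.00766), so the call rests on the background, which was widened after the data were examined.

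Genes of mRNA splicing carried promoter peaks in myoblasts more often than other genes. Of 15 members named in the lists 9 had a peak (60.0%, 32.3 to 83.7%), namely SRSF1, SRSF2, SRSF5, SRSF6, SRSF7, HNRNPAB, HNRNPM, HNRNPR and PTBP1, against 21.9% of other genes (odds ratio 5.36, Fisher exact test, adjusted p = 0.0397 over 25 lists). SRSF1, a serine- and arginine-rich splicing factor, had 23.1 tags per 10M with 0 IgG tags, on chromosome 19 from 8706327 to 8706527. SRSF5 had 15.3 and PTBP1, the polypyrimidine tract binding protein, 13.9. With curated genes as the background the share was 42.9% against 14.6% (exact test, adjusted p = 0.0428). Members were matched by exact symbol, a choice made after first results were seen. By the same exact test the call was lost with a 5 kb window (adjusted p = 0.741) and in the upper 50% of peaks by score (adjusted p = 0.223). No other list passed in myoblasts, and 3 lists had an unadjusted p under 0.05.

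Histone and clock genes came next by share. Of 9 histone genes 5 had a promoter peak (exact test, adjusted p = 0.252): H3F3B, which encodes variant histone H3.3, at 17.9 tags per 10M, HIST1H46 at 15.7, HIST1H2B7 at 14.8, and H3F3C and H2AFZ at 12.6. Of 12 circadian E-box genes 6 had one (exact test, adjusted p = 0.252), with CRY1, a repressor of the clock, at 20.9, RORA at 16.1, TEF at 15.3 and PER3 at 13.1. Cell cycle genes followed with 6 of 14, including CCNB3 at 17.0, CDK6 at 14.8 and PLK1 at 14.4. The MYC network, described below, had the same share, with 3 of 7. Proteasome and chaperone genes had 7 of 17, with HSPA8 at 14.4 and PSMB1 at 13.1, and ribosomal protein genes had 9 of 25, with RPS3A at 26.1, RPL19 at 18.3, RPS10 at 17.9 and RPS24 at 16.6. The cell cycle, proteasome and chaperone, and ribosomal protein lists did not pass the exact test (adjusted p = 0.402 for each).

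**Figure D3:**
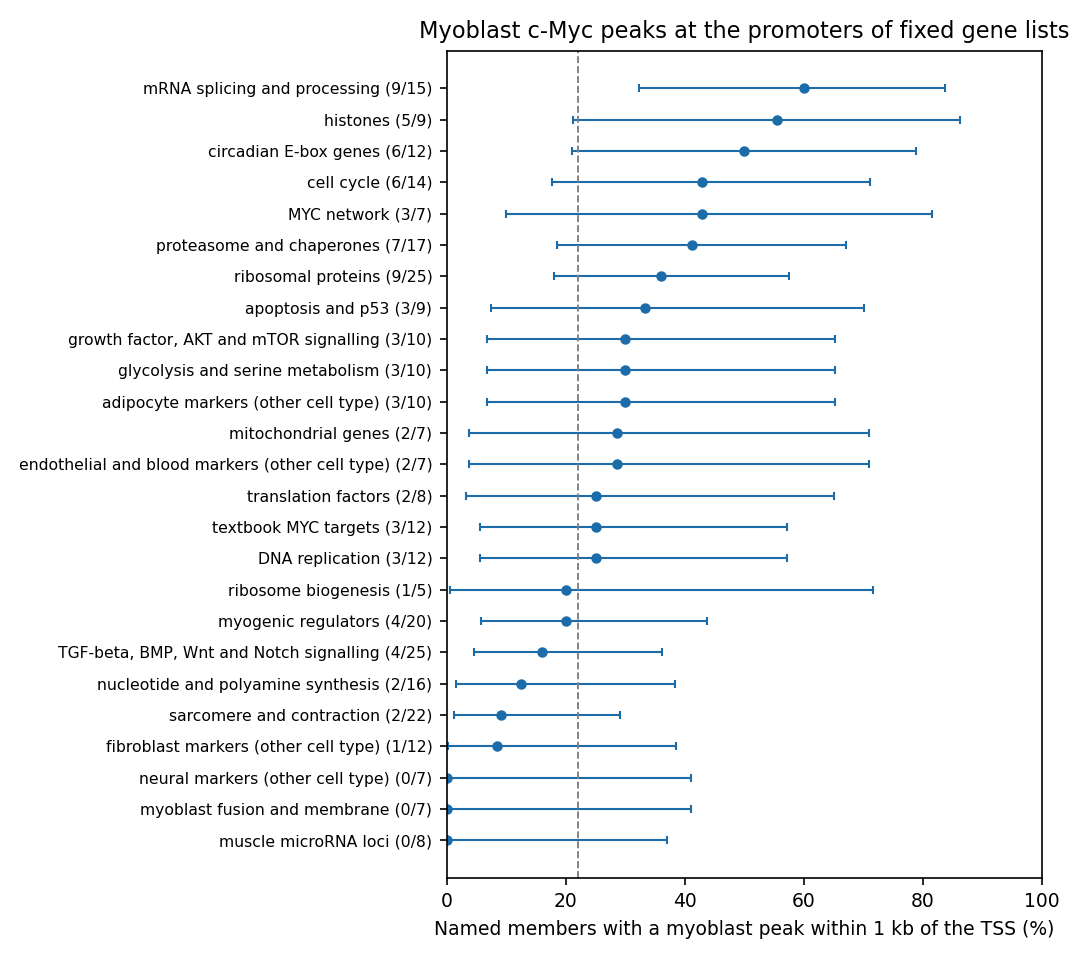
Share of the members of 25 gene lists named in the peak lists that had a myoblast c-Myc peak within 1 kb of the TSS (x axis, percent, with exact 95% binomial intervals), with counts in brackets; the dashed line marks the share among all 4834 named genes, 22.0%. mRNA splicing is the list whose interval lies wholly above that line.

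Textbook targets of MYC did not pass the test in either list. Of 12 named members 3 had a promoter peak in myoblasts, CDC25A, NCL (15.7 tags per 10M) and LDHA (15.3), against 22.0% of other genes (exact test, adjusted p = 0.797). The interval of that share, 5.49 to 57.2%, leaves room for a large excess. In myotubes CDC25A had one, 8.33% of members against 1.35% of other genes (exact test, unadjusted p = 0.152, adjusted p = 1.00). Ribosome biogenesis had 1 of 5, NCL, translation factors 2 of 8, EIF2S2 (19.2) and EIF4G2 (15.7), and nucleotide and polyamine synthesis 2 of 16, AMD1 (19.6) and UMPS (11.8). Glycolysis and serine metabolism had 3 of 10, LDHA, GPI (13.9) and PGK1 (12.6), DNA replication 3 of 12, MCM2 (13.5), RFC3 (13.1) and MCM6 (11.8), and mitochondrial genes 2 of 7, NDUFS1 (16.6) and COX4I1 (15.7). Growth factor, AKT and mTOR signalling had 3 of 10, led by the kinase AKT1 (23.1) and RPS6KB1 (15.3), with IGF1 at 10. TGF-beta, BMP, Wnt and Notch signalling had 4 of 25, NOTCH2 (18.7), TGFBR1 (17.9), BMP4 (17.0) and CTNNB1 (13.1). Apoptosis and p53 genes had 3 of 9, BID (16.6), FAS (14.8) and MDM2 (13.1).

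Muscle structural genes did not differ from other genes by the test used. Of 22 sarcomere and contraction genes 2 had one in myoblasts, TNNC1, the slow and cardiac troponin C (13.9 tags per 10M), and CASQ2, a calcium store protein (12.6), a share of 9.09% against 22.0% of other genes that did not pass the exact test (adjusted p = 0.592). Within 5 kb the direction turned, with 50% of these genes against 40.5% of others. Myoblast fusion and membrane genes had 0 of 7, which allows a share of up to 41.0%. Muscle microRNA loci, with distances taken from the start of the precursor, had 0 of 8, which allows up to 36.9%. Among markers of other cell types, fibroblast genes had 1 of 12, COL3A1 (13.5), adipocyte genes 3 of 10, CEBPB (14.8), LEPR (11.8) and PPARG (10.9), endothelial and blood genes 2 of 7, HBZ (13.5) and TAL1 (11.8), and neural genes 0 of 7.

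In myotubes 6 of the 25 lists had any member with a promoter peak, and none passed the test. Mitochondrial genes had 2 of 7, COX4I1 (16.2 tags per 10M) and HSPA9, the mitochondrial chaperone mortalin (12.1), with an unadjusted Fisher exact p = 0.00369 and an adjusted p = 0.0922. Textbook MYC targets and cell cycle genes had CDC25A alone (12.7), listed ribosomal proteins RPL32 (13.9), mRNA splicing SRSF6 (15.6) and proteasome and chaperones HSP90AA1 (11.6). RPL12, a ribosomal protein outside the list, also had a myotube promoter peak (12.1). The other 19 lists had none, and with 66 target genes in all, a list of 20 members at the general share would hold fewer than 1.

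The gene for c-Myc itself had no peak near its promoter. MYC was the nearest gene of 31 myoblast peaks and 3 myotube peaks, but the closest lay 63.5 kb and 260.3 kb from its TSS, in intergenic sequence. Among its network, MYCN, a paralog, had a myoblast peak 741 bp downstream of the TSS (11.8 tags per 10M), and the MAX partners MXD1 and MXD4, which antagonise MYC, had peaks at -877 and -398 bp (13.5 and 13.9). MXI1 had a peak in intron 1, 4.36 kb from the TSS, whereas the closest peaks of MLX and ZBTB17 lay 28.5 and 35.6 kb away. The share of 3 of 7 did not pass the exact test (adjusted p = 0.592), and in myotubes no network gene had a peak within 5 kb.

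The myogenic determination genes lacked promoter peaks in both states. The closest myoblast peaks lay 82.6 kb from MYOD1, 19.0 kb from MYF5 and 12.5 kb from MYF6, and none was assigned to these genes in myotubes, while MYOG, the gene for myogenin, was nearest to no peak of either list. Promoter peaks in myoblasts stood at ID3, an inhibitor of helix-loop-helix factors (16.1 tags per 10M, at -3 bp), EYA2, a transcriptional cofactor (16.1), TWIST1, a repressor of myogenesis (15.3), and MEF2A, a factor of muscle gene expression (14.4). These were 4 of 20 named myogenic regulators (20%, exact test, adjusted p = 1.00). SRF had its closest peak at 3.4 kb, PAX3 and PAX7 in introns at 11.5 and 21.1 kb, MEF2D in an intron at 20.7 kb, and SMYD1 and TWIST2 at 5.88 and 6.95 kb. ID1, ID2, ID4, TCF12 and FST had none closer than 13.9 kb. In myotubes 7 peaks were nearest to a myogenic regulator, at TCF3 (intron, 8.55 kb from the TSS), TWIST2 (10.2 kb), MEF2A (30.3 kb), EYA2 (33.1 kb) and PAX7 (intron, 44.6 kb).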

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

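Alternatives on repeats, the curated gene background, shifted peaks and the chromosome classes other than by the upper 50% by score were chosen after seeing the data. No paired analysis was possible because each group held 1 library, and leaving out a library was not possible. The planned E-box alternatives were not run, for want of the genome sequence. Unplaced and mitochondrial sequence held 0 peaks, so leaving it out moved nothing and tests nothing. Depth limits all lists: the typical peak held 14.5 tags in myoblasts and 11.5 in myotubes. Of 287 alternative values, 226 kept their direction and side of the threshold or their size. For the others the cause was not tested unless stated. The 226 include values that could not change, such as those without unplaced sequence. Leaving out repeats and structural RNA genes also cannot alter the gene list tests, since no peak within 1 kb of a TSS was labelled as such.

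A fold over IgG of at least 16.1 left 4504 myoblast and 297 myotube peaks, still a 15.2-fold difference. Shared peaks passed the permutation test at p = 0.000999 under every alternative, but in some the number of shared peaks moved by more than 1.5 times. There were 140 against a random mean of 44.4 at centres within 1 kb, 49 against 2.55 in the upper 50% of each list by score, 46 against 0.469 for the 1061 strongest myoblast peaks and 39 against 7.61 without repeats. The promoter share in myotubes and myoblasts was 4.24% and 4.31% within 500 bp, where the difference of myotube-only peaks turned to -0.763 percentage points, and 13.9% and 11.6% within 5 kb, by construction of the window. In the upper 50% by score the difference was -0.214 and the myoblast share 7.24%; against the strongest myoblast peaks it was -7.83, at a myoblast share of 14.2%, and 2 annotation classes differed. The microchromosome difference was 3.35 percentage points in the upper 50% (Fisher exact p = 0.0664) and -5.37 against the strongest myoblast peaks (Fisher exact p = 0.00908).

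Genes with a promoter peak numbered 1961 in myoblasts, 144 in myotubes and 56 in both within 5 kb, below the 58.4 of independent lists. With the nearest gene at any distance they numbered 4768, 886 and 820, below 873.9, because the background then consists of the genes counted. The upper 50% left 41 myotube genes and 7 in both, and the strongest myoblast peaks 150 myoblast genes and 2 in both, against 2.05. With curated genes as background the 18 in both passed (Fisher exact p = 0.00766). In myoblasts 0 lists passed within 5 kb, in the upper 50%, or with the nearest gene at any distance, where 98.6% of genes are targets and the tests of single lists can hardly tell anything.

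mRNA splicing had 60.0% against 40.5% of other genes within 5 kb, a smaller excess, and 40% against 15.1% in the upper 50%, both without passing. The following lists, none of which passed in any setting, changed sides of the share of other genes. In myoblasts within 5 kb these were ribosome biogenesis (60.0%), translation factors (25%), fusion (42.9%), sarcomere (50%), fibroblast (50%) and adipocyte genes (40%). In the upper 50% they were ribosome biogenesis (20%), myogenic regulators (20%), TGF-beta and Notch signalling (16%), adipocyte (10%) and endothelial and blood genes (14.3%). With curated genes they were translation factors (14.3%), mitochondrial genes (12.5%), myogenic regulators (16.7%) and TGF-beta and Notch signalling (14.8%). In myotubes with the nearest gene at any distance they were textbook MYC targets (16.7%), nucleotide synthesis (25%), glycolysis (20%), myogenic regulators (25%), fusion (57.1%), growth factor signalling (30%), TGF-beta and Notch signalling (24%), circadian (25%) and adipocyte genes (20%), and in the upper 50% textbook MYC targets, cell cycle and proteasome genes (0%).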

Other observations

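The words of gene descriptions, the tests of depth and of IgG in repeats, and the test without repeats were chosen only after the results were seen. The comparison of tags between promoter peaks and other peaks was not among the tests fixed beforehand.

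Among 121 words found in the descriptions of at least 20 genes, 4 were more frequent among myoblast target genes than among other named genes and 2 were less frequent (two-sided Fisher exact tests, adjusted over the words). Of 21 genes described as histone genes or histone modifiers 12 had a promoter peak (57.1%, exact test, adjusted p = 0.0137), of 192 described as a subunit 67 (34.9%, adjusted p = 0.00219), of 94 described as part of a complex 36 (38.3%, adjusted p = 0.0137) and of 129 named as homologs of a yeast gene of S. cerevisiae 44 (34.1%, adjusted p = 0.0327), against 22.0% of all genes. Receptors were targets less often, 51 of 346 (14.7%, exact test, adjusted p = 0.0137), and so were microRNA genes, 45 of 505 (8.91%, adjusted p = 5.96e-14). For microRNA genes the distance is taken from the start of the precursor, which need not be their promoter. Their share therefore does not show that their promoters had fewer peaks. Genes were counted here by words, and many words share genes.

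Promoter peaks had more tags than other peaks, clearly in myoblasts and less so in myotubes. Outside repeats and structural RNA genes, 2.40% (1.76 to 3.19%) of the weakest 10% of myoblast peaks lay within 1 kb of a TSS and 13.0% (11.6 to 14.6%) of the strongest 10%. In myotubes these shares were 6.93% (2.83 to 13.8%) and 10.9% (5.56 to 18.7%), with overlapping intervals. Median tags per 10M were 13.5 at promoter peaks and 12.6 at other peaks in myoblasts (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give), and 13.9 and 13.3 in myotubes (p = 0.0356). IgG tags per 10M had a median of 1.87 at promoter peaks and 1.55 at other peaks of myoblasts. IgG was thus higher at promoter peaks too, and the higher c-Myc tags do not show a greater enrichment over IgG there.

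The myotube list was 18.2 times shorter than the myoblast list. Lower depth of the myotube library as the whole cause is argued against: its c-Myc total was 0.754 of that in myoblasts, and of 8748 myoblast peaks outside repeats whose tags, scaled to that depth, still reached 11, the lowest caller score in the myotube list, 30 met a myotube peak (0.343%, 0.231 to 0.489%). Of the 192 myoblast peaks outside repeats with at least 20.8 tags per 10M, 9 did (4.69%, 2.17 to 8.71%). Of the 1772 that still reached 11 after scaling to the narrower peak width as well, 16 did (0.903%). In number, the 8748 peaks were 8.25 times the myotube list, but the 1772 were 1.67 times it. Scaling for depth and width together thus left a much smaller difference in number than 18.2-fold, while the overlap stayed low. Scaling by width takes tags as spread evenly over a peak. A weaker immunoprecipitation could also shorten the list, and it cannot be told apart from a loss of c-Myc binding: the median ratio of myotube to myoblast tags at shared peaks was higher by 0.0456 outside repeats than inside (0.837 and 0.792, two-sided permutation p = 0.351), among peaks that had passed in both libraries, with no correction for peak width. Peak calling options are not given, peak widths and lowest caller scores (12 and 11) differ between the lists, and unequal settings could change the number of peaks by themselves; this was not tested, and the difference between the cell states stays open, untested without replicates.

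The 10 peaks with the most tags lay in simple repeats or rRNA genes in both lists, the strongest on chromosome 20 in a TG repeat, with 297.2 tags per 10M in myoblasts and 214.4 in myotubes. Multi-copy sequence that collects reads whatever the antibody is a candidate explanation: the lowest IgG level among these peaks was 6.06 times the mean IgG density in myotubes and 7.78 times in myoblasts. Over all peaks in repeats or structural RNA genes, IgG was 1.40 times that at other peaks in myoblasts and 2.67 times in myotubes (one-sided permutation p = 2e-05 and 1e-05). Every listed peak had at least 4.0 times the scaled IgG, so peaks with few c-Myc tags could hold little IgG. That limit partly sets this comparison between peaks. The peaks in repeats passed it too, so a further contribution of c-Myc is not excluded, and no biological explanation was tested.

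The 74 shared peaks exceeded random placement, and repeats or promoters could account for this in part. Without peaks labelled as repeats or structural RNA genes 39 shared peaks were left, above the 18 that was the highest of 1000 random placements. Each peak carries a single label, and no peak within 1 kb of a TSS had such a label, so repeats under promoter peaks were not removed. Without any labelled repeat and any peak within 1 kb of an annotated TSS 28 were left, above 17. That limit does not remove the shared myotube peaks at WWC1, ABTB1 and C21H1ORF144, classed as promoter at 1227, -1092 and -1732 bp, or peaks at unannotated promoters. A pair is also lost where its myoblast peak is left out. Labelled repeats alone, or peaks within 1 kb of an annotated TSS alone, therefore do not give the excess. A shift of each myotube peak by 5 to 50 kb met 9.61 myoblast peaks on average, so clustering of peaks at the scale of these shifts does not give the excess either. Clustering finer than 5 kb is removed by such shifts and was not tested. c-Myc binding at the same sites in both cell states may explain the rest, as a hypothesis; open chromatin and poorly mapped sequence outside annotated repeats were not tested.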
